A study of Mus musculus with 4 samples.

How the data were processed

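RNA from 2000 sorted mouse bone marrow cells per sample was amplified, labelled with biotin and hybridised to Affymetrix MOE430_2 arrays, per the labels and the design text of the series. The 4 samples form 2 groups of 2, CLP_RAGhigh and CLP_RAGlow, taken from the sample titles. The deposited values are expression values from the RMA algorithm per the labels' series design, 1 value per probe set, in units of intensity. RMA corrects the background, normalizes between arrays and summarises the probes of each set. The software, its version and any further filter are not given in the sources used here. RMA values usually come as log2, but the deposited intensity values ran from 2.35 to 19892, which fits a linear scale, and log2 was taken here. The quantities measured by RMA below the background are not separated from low expression, and no detection calls were used here.

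Dual amplification from few cells copies mostly the 3' ends of transcripts, which makes the ratio of 3' to 5' probe sets larger. For Actb this ratio was 16.2 and 9.62 on the CLP_RAGhigh arrays (replicates 1 and 2) and 13.5 and 24.5 on the CLP_RAGlow arrays, and for Gapdh 15.7, 10.6, 14.0 and 20.0. Hybridisation controls (9 probe sets) averaged 1690, 3399, 1767 and 1681 in the same order, so that CLP_RAGhigh replicate 2 was 1.99-fold above the mean of the other 3 arrays. The poly-A controls (12 probe sets) averaged 1392, 1572, 1129 and 1023. Median intensities were 14.6, 14.8, 14.9 and 14.7. The precision is limited by the number of arrays.

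The table held 45101 rows, of which 64 were control probe sets and were left out. Of the other 45037 probe sets, 34945 were assigned to 1 gene by the platform annotation, 932 to several and 9160 to none, and the last 2 kinds were not used. Gene IDs of 34741 probe sets were found in the reference table, 204 were not, and 0 symbols had to be updated. For each gene the probe set with the highest mean log2 value over the 4 arrays was kept, which gave 18193 genes. Genes with a group mean below 3.90, the median log2 value of all probe sets, are called dim in the text, and for these a difference after adding an offset of 32 on the linear scale is printed as well, since the fold of a dim gene depends on the background. Of the named genes, 53 had several probe sets, which went in 1 direction for 30 genes and not for 23. With the probe sets averaged, the difference of 20 of these 53 genes was under 50% of the printed one or of the other sign. No genome build is given in the sources used here, so no coordinates are printed.

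Differences between the groups were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 2 residual and 3.75 prior degrees of freedom. Printed differences are CLP_RAGhigh minus CLP_RAGlow, with the standard error from the fit. Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over 18 lists, and again with a correlation estimated from the residuals and with fry. With the estimated correlation and with fry's directional test, 0 lists passed. Fry's mixed test, which asks whether genes of a list change in either direction, had adjusted p under 0.05 for 6 lists, B-lineage transcription factors (0.0108), stem and multipotent progenitor genes (0.0114), pre-B-cell receptor and B-cell signalling (0.0303), and V(D)J recombination, T-lineage and mature B genes (0.0398 each). In the main text every p of camera is adjusted over the 18 lists. Figures were drawn with matplotlib 3.10.9.

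The gene lists, the tests of genes and lists, the rule for naming genes and all but 2 alternatives were fixed before the data were examined. Those 2 alternatives and part of the tests in the closing section were chosen afterwards, as said there. The lists held 360 genes, of which 330 were measured and 30 were not analysed here, and they covered V(D)J recombination, B-lineage, T-lineage, natural killer, dendritic, granulocyte, erythroid, stem, lymphoid-primed, cell cycle, interferon, stress, BCL2, MYC, mature B and stromal genes, with a list of sex-linked genes as a check of the animals. The genes named are Rag1, Rag2 and Dntt, then in each direction up to 12 genes past the threshold with the largest differences, filled to 8 by the moderated statistic among genes whose groups do not overlap where too few pass, then up to 4 genes of each list with the smallest p, and the sex-linked genes. None passed over all genes, so 8 per direction are given as values. Genes outside this rule are said to have been chosen after their values were seen.

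Both steps were tested on simulated data with the real means and spread, 10 tables of 18193 genes, of which 17993 were unchanged in each. Genes were simulated independently of each other, and the changed genes were drawn only from those above the median brightness. For CLP_RAGhigh against CLP_RAGlow, limma called 1% of genes changed 2-fold, 7.8% of those changed 4-fold, 38.4% of those changed 8-fold and 73.4% of those changed 16-fold, and 6.07% of its calls were false. Camera with the preset correlation called a list shifted by 1 log2 unit in 10 of 10 tables and 0 unshifted lists, while camera with an estimated correlation called the shifted list in 0 of 10 tables. As the simulated genes did not vary together, this does not show how often the preset correlation gives false calls on real lists. The estimated correlation of the G2 and M phase genes, for example, was 0.545.

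The alternatives tried were other variance models, other rules for the probe set of a gene, filters on dim genes, median centring, a second quantile normalization, an offset before log2, the replicate number as a block, other thresholds, each array left out in turn, camera on ranks, fry and the estimated correlation. The labels number the replicates 1 and 2 in both groups and do not say that a number marks a shared animal or sort, so the main test has no block. Where 1 array of a group is left out, the lone array is assumed to vary like those of the other group. Nothing was left out of the samples.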

Results

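Gene expression was measured on 4 mouse arrays, with 2 of CLP_RAGhigh and 2 of CLP_RAGlow cells. Both are subpopulations of the common lymphoid progenitor (CLP), the bone marrow progenitor that gives rise to B cells, T cells, natural killer cells and some dendritic cells. They were sorted from the bone marrow of adult C57Bl6 mice 8 to 12 weeks old. The sample descriptions name the sorted fractions by a high or low level of GFP, and the groups carry the name of RAG, the enzyme that cuts antigen receptor genes during V(D)J recombination. The design implies 1 comparison, of which genes and gene groups differ between the RAGhigh and the RAGlow progenitors. Each array had a median deposited intensity between 14.6 and 14.9, and 18193 genes were compared. The number of arrays limits the precision of every value below. The labels call the replicates biological but do not say whether they came from separate animals or sorts, so the p-values measure only the spread between these samples.

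The sorting label was checked first. Rag1, the catalytic subunit of the recombinase, had a mean log2 intensity of 10.77 ± 0.21 in CLP_RAGhigh and 8.13 ± 0.57 in CLP_RAGlow (SD, n = 2 each), a difference of 2.65 ± 0.34 (SE) or 6.26-fold. Both CLP_RAGhigh arrays lay above both CLP_RAGlow arrays, and the limma adjusted p over all genes was 0.256. Its partner Rag2 differed by 0.89 ± 0.33 in the same direction. Dntt, which adds nucleotides at the joined ends, was bright in both groups, at 13.48 and 13.41, with a difference of 0.06 ± 0.06. Its 3 probe sets ran from 0.057 to 0.79, and their average gave 0.30. The labels do not describe the reporter or say whether it alters a Rag gene, so the Rag1 values are given only as a check of the group names.

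As gene lists tested by limma's camera with its preset correlation, genes of the B lineage were higher in CLP_RAGhigh, and stem and multipotent progenitor genes and cell cycle genes were higher in CLP_RAGlow. With an estimated correlation 0 lists passed. In the simulated tables, however, this form of camera called a list shifted by 1 log2 unit in 0 of 10 tables. A p above the threshold from it therefore does not show that a list did not shift. Genes of pre-B-cell receptor and B-cell signalling had a median log2 difference of 0.61 over 20 measured genes (adjusted p = 0.348 with an estimated correlation), with Vpreb1, which encodes part of the surrogate light chain, at 3.13 ± 0.28 (SE, n = 2 per group). For B-lineage transcription factors, with Ebf1 at 3.65 ± 0.54, adjusted p with an estimated correlation was 0.634. The G2 and M phase genes, with a median of -1.25 over 23 genes, and the stem and multipotent progenitor genes, with a median of -0.35 over 24 genes, had the same adjusted p of 0.634. Leaving out 1 array also ended calls made with the preset correlation, those of the B-lineage transcription factors (adjusted p = 0.226) and S phase genes (adjusted p = 0.590) without CLP_RAGhigh replicate 1, and that of the stem and multipotent progenitor genes (adjusted p = 0.0709) without CLP_RAGhigh replicate 2. The call of the remaining list, immediate early and stress genes upward, was lost without CLP_RAGhigh replicate 1 (adjusted p = 0.765) and without CLP_RAGlow replicate 2 (adjusted p = 0.190). No single gene passed the threshold across all genes, so the calls rest on gene lists.

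Single genes were compared with limma. At an adjusted p under 0.05, 0 genes were higher in CLP_RAGhigh and 0 were higher in CLP_RAGlow. At an unadjusted limma p under 0.05, 428 genes were higher in CLP_RAGhigh and 535 in CLP_RAGlow, where chance gives 455 in each direction. The arrays of the groups did not overlap for 15.4% of genes above and 15.8% below, where chance gives 16.7% each way. At an adjusted p under 0.1, 6 genes lay above and 2 below. Correlations across genes, which are not independent replicates, were 0.963 within CLP_RAGhigh, 0.976 within CLP_RAGlow and 0.963 to 0.969 between the groups.

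The genes of pre-B-cell receptor and B-cell signalling had the highest median difference and the smallest upward camera p of the 18 lists, while by mean difference the B-lineage transcription factors stood higher (0.97 against 0.86). Of 20 measured genes, 17 had a higher mean and 3 a lower mean in CLP_RAGhigh, and 12 had both CLP_RAGhigh arrays above both CLP_RAGlow arrays, where chance gives 3.33. The list passed with camera (adjusted p = 7.4e-10 with the preset correlation), and it had adjusted p = 0.348 with an estimated correlation. That correlation was -0.0080, below the preset 0.01, so the larger p does not come from genes of the list that vary together. With p-values adjusted over the list alone, 6 genes passed, all higher in CLP_RAGhigh, and 0 passed over all genes. They were Vpreb1, Ly6d, Cd79a, Blk, Blnk and Vpreb3, of which Blnk and Vpreb3 were named after their values were seen. Vpreb1 had mean log2 intensities of 10.56 in CLP_RAGhigh and 7.43 in CLP_RAGlow, Ly6d, a surface marker of B-cell-biased progenitors, 8.80 and 6.30, and Cd79a, a signalling chain of the B-cell receptor, 6.11 and 4.06. The kinase gene Blk differed by 2.15 ± 0.47, and Blnk, an adaptor of the same pathway, by 1.30 ± 0.30. Vpreb3, which assists assembly of the receptor, had means of 6.10 and 4.60.

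**Figure D1:**
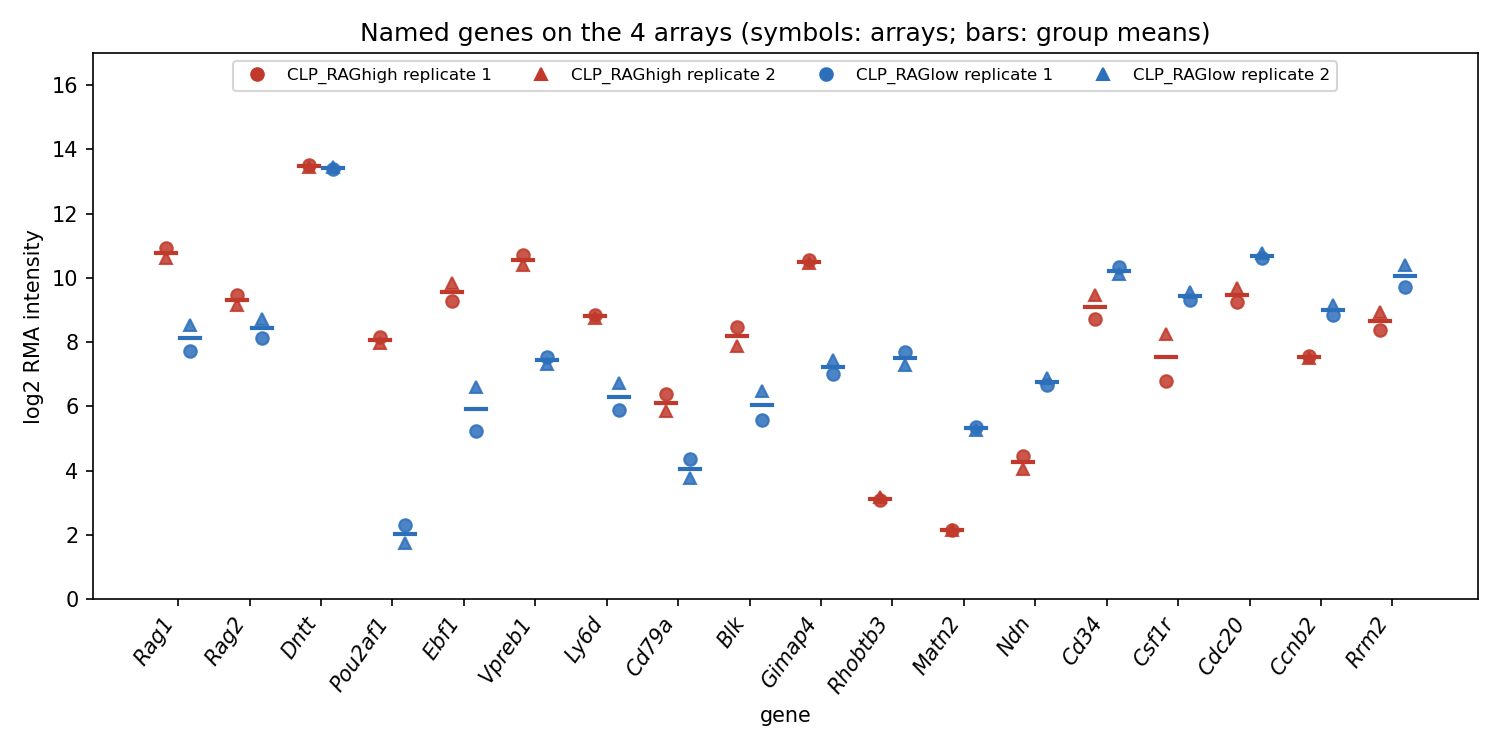
Log2 RMA intensity (vertical axis) of 18 genes on each array, with circles for replicate 1, triangles for replicate 2, red for CLP_RAGhigh, blue for CLP_RAGlow and bars for the group means. Dntt lies near 13.48 and 13.41 in the groups, while Rag1 lies at 10.77 and 8.13 and Vpreb1 at 10.56 and 7.43.

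B-lineage transcription factors had a median log2 difference of 0.31 over 16 genes, 12 with a higher and 4 with a lower mean in CLP_RAGhigh. The arrays separated for 7 genes above and 2 below, where chance gives 2.67 each way. The list passed with camera (adjusted p = 0.00022) and had adjusted p = 0.634 with an estimated correlation. Adjusted over the list alone, 2 genes passed, both higher in CLP_RAGhigh, and 0 passed over all genes. Pou2af1, a coactivator of octamer-binding factors in B cells, had means of 8.07 and 2.03, and Ebf1, which sets the early B-cell programme, had means of 9.57 and 5.92. Irf4 differed by 1.99 ± 0.58 (0.99 with an offset of 32 before log2, as it is dim in CLP_RAGlow) and Bach2 by 1.01 ± 0.37 (0.37 with probe sets averaged), and neither passed. The list's median was 0.18 without CLP_RAGhigh replicate 1, with adjusted p = 0.226. That array was also the one with high immediate early genes described below.

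The largest moderated differences toward CLP_RAGhigh included genes of several kinds, and none of them passed over all genes. Pou2af1 had the smallest limma adjusted p, 0.0620, with a log2 difference of 6.04 ± 0.35 (SE, n = 2 per group). Its CLP_RAGlow values lay among the dimmest probe sets of the array, so that the size of the difference depends on the background. With an offset of 32 before log2 the difference was 3.05. Gpat3, an enzyme of triglyceride synthesis, differed by 5.05 ± 0.34 (2.75 with the offset), and Map9, a microtubule-associated protein, by 4.34 ± 0.37 (2.31 with the offset and 1.57 with its probe sets averaged). Gimap4, of the GTPases of immunity-associated proteins, was bright in both groups, at 10.50 and 7.23, and differed by 3.27 ± 0.29. Zfp563 differed by 3.50 ± 0.31 (1.47 with the offset), Scn4b, a sodium channel subunit, by 4.07 ± 0.45 (2.08 with the offset), and Aldh1a1, a retinaldehyde dehydrogenase, by 1.66 ± 0.20 (0.32 with the offset).

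Toward CLP_RAGlow, Matn2, an extracellular matrix protein, had the smallest limma adjusted p, 0.0687, with a log2 difference of -3.17 ± 0.23 (-0.98 with the offset of 32). Rhobtb3 had a difference of -4.36 ± 0.34 (-2.38 with the offset), which was -1.31 with its probe sets averaged and -0.16 without probe sets marked as cross-hybridising. Averaging gave -1.83 for Matn2. The germ-cell helicase gene Ddx4 had means of 4.09 in CLP_RAGhigh and 8.57 in CLP_RAGlow, and Cenpp, a centromere protein, differed by -2.66 ± 0.36. Slc18b1, Ell2, 1700012D14Rik and Spsb4 differed by -1.91, -2.68, -2.04 and -2.49. All 4 of these had CLP_RAGhigh values among the dimmest probe sets, and with the offset their differences were -0.41, -0.89, -0.59 and -0.79. For Ell2, Rhobtb3 and 1700012D14Rik, 1 probe set of the gene went the other way, and averaging gave -1.27 for Ell2 and -0.80 for 1700012D14Rik.

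Stem and multipotent progenitor genes were lower in CLP_RAGhigh with the preset correlation only. Of 24 measured genes, 19 had a lower and 5 a higher mean in CLP_RAGhigh, and 10 were separated below against 1 above, where chance gives 4 each way. The list passed with camera (adjusted p = 0.00036) and had adjusted p = 0.634 with an estimated correlation. When genes below the median brightness were left out, camera with the preset correlation gave adjusted p = 0.0439, with a median of -0.35. The call thus rested in part on dimmer genes. Adjusted over the list alone, 2 genes passed, both lower in CLP_RAGhigh, and 0 passed over all genes. Ndn, an imprinted growth suppressor, fell by 2.51 ± 0.35 on the log2 scale, with a difference of -5.02 without cross-hybridising probe sets and 8 probe sets that ran from -5.06 to 0.026, and Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, fell by 1.33 ± 0.26 (a difference of -0.45 with the offset of 32, since it is dim in CLP_RAGhigh). Cd34, a surface marker of early progenitors, had means of 9.10 and 10.22, a difference of -1.12 ± 0.32 that did not pass, and Hoxa10 differed by -0.79 ± 0.27 (-0.22 with the offset and -0.28 with probe sets averaged). Without CLP_RAGhigh replicate 2 the list's median was -0.22, with adjusted p = 0.0709.

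Cell cycle genes were lower in CLP_RAGhigh in both lists that covered them, with the preset correlation only. Of 23 genes of the G2 and M phases, 21 had a lower and 2 a higher mean in CLP_RAGhigh, and 13 were separated below, where chance gives 3.83. The list passed with camera (adjusted p = 8.4e-11) and had adjusted p = 0.634 with an estimated correlation, which was 0.545 for these genes. Adjusted over the list alone, Cdc20, an activator of the anaphase-promoting complex, and Ccnb2, a mitotic cyclin, passed, and 0 genes passed over all genes. Cdc20 fell by 1.23 ± 0.24 and Ccnb2 fell by 1.46 ± 0.31, while Aurkb and Tpx2 differed by -1.25 ± 0.36 and -2.11 ± 0.61 without passing (-0.86 for Tpx2 with its probe sets averaged). The list's deviation from each gene's mean was -0.92 on CLP_RAGhigh replicate 1, -0.07 on CLP_RAGhigh replicate 2, 0.10 on CLP_RAGlow replicate 1 and 0.95 on CLP_RAGlow replicate 2. The median difference was -0.52 without CLP_RAGhigh replicate 1 (adjusted p = 0.00171) and -0.82 without CLP_RAGlow replicate 2 (adjusted p = 0.000335).

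DNA replication and S phase genes had a median difference of -0.40 over 24 genes, 18 with a lower and 6 with a higher mean in CLP_RAGhigh, and 11 were separated below, where chance gives 4. The list passed with camera (adjusted p = 0.000305) and had adjusted p = 0.708 with an estimated correlation. Adjusted over the list alone 0 genes passed, and 0 passed over all genes with limma, while 4 had an unadjusted limma p under 0.05, all lower in CLP_RAGhigh. These were Rrm2, a subunit of ribonucleotide reductase, at -1.40 ± 0.35, Rfc3 at -1.37 ± 0.40, Pcna, the sliding clamp of replication, at -0.62 ± 0.21, and Mcm5, of the replicative helicase, at -0.45 ± 0.18. The call rested on CLP_RAGhigh replicate 1, since without it the median was -0.02, with adjusted p = 0.590. For Rrm2 the probe sets disagreed, at -1.40 and 0.05 as the lowest and highest.

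**Figure D2:**
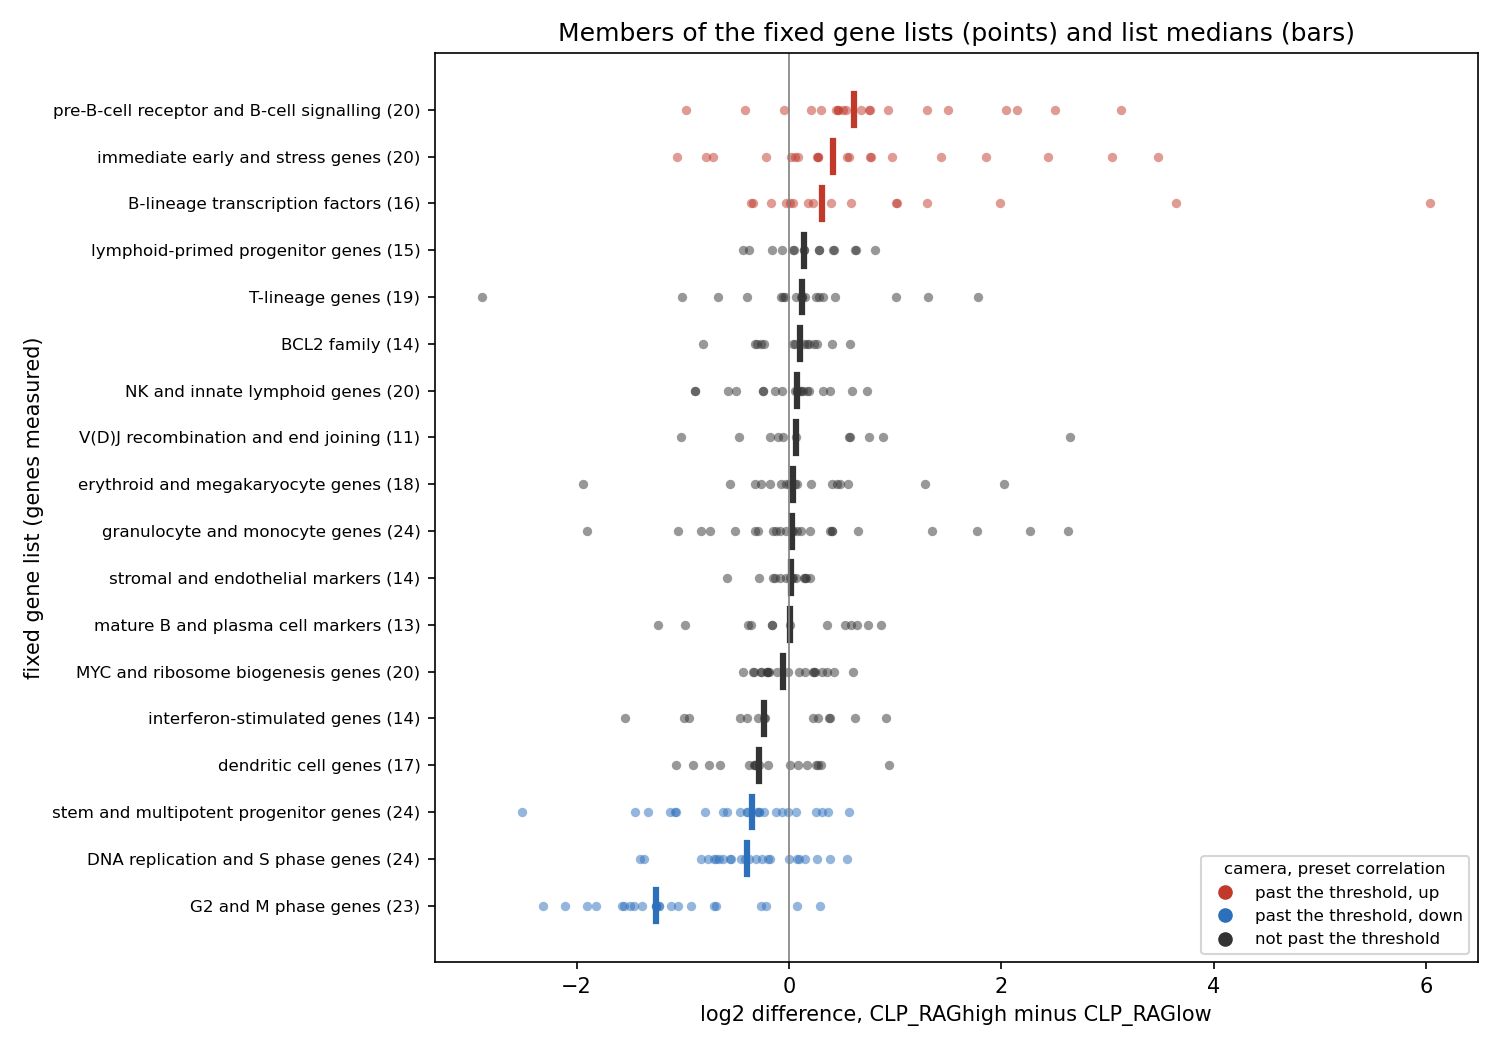
Log2 difference, CLP_RAGhigh minus CLP_RAGlow (horizontal axis), of each measured gene of the 18 fixed lists (points) with the list medians (bars), red for lists past the camera threshold upward, blue for those past it downward and dark grey for the others. The list medians run from -1.25 for the G2 and M phase genes to 0.61 for pre-B-cell receptor and B-cell signalling.

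Immediate early and stress genes passed with camera upward (adjusted p = 0.0451), and had adjusted p = 0.785 with an estimated correlation. Of 20 genes, 16 had a higher and 4 a lower mean in CLP_RAGhigh, but only 4 were separated above, where chance gives 3.33. With limma 0 genes passed over the list alone or over all genes. At an unadjusted limma p under 0.05 there were 0 genes higher in CLP_RAGhigh and 1 lower, Gadd45b. Fos, a transcription factor subunit induced within minutes of stimulation or handling, had a log2 intensity of 12.27 on CLP_RAGhigh replicate 1, 7.13 on CLP_RAGhigh replicate 2, and 7.28 and 5.17 on the CLP_RAGlow arrays. Gadd45b, at -1.05 ± 0.34 (-0.53 with probe sets averaged and -0.31 without cross-hybridising ones), went the other way. Ier2 and Junb differed by 0.76 ± 0.35 and 0.97 ± 0.48 (0.34 for the dim Junb with the offset). Without CLP_RAGhigh replicate 1 the list's median was 0.09 with adjusted p = 0.765 and a test direction downward, and without CLP_RAGlow replicate 2 it was 0.33 with adjusted p = 0.190.

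**Figure D3:**
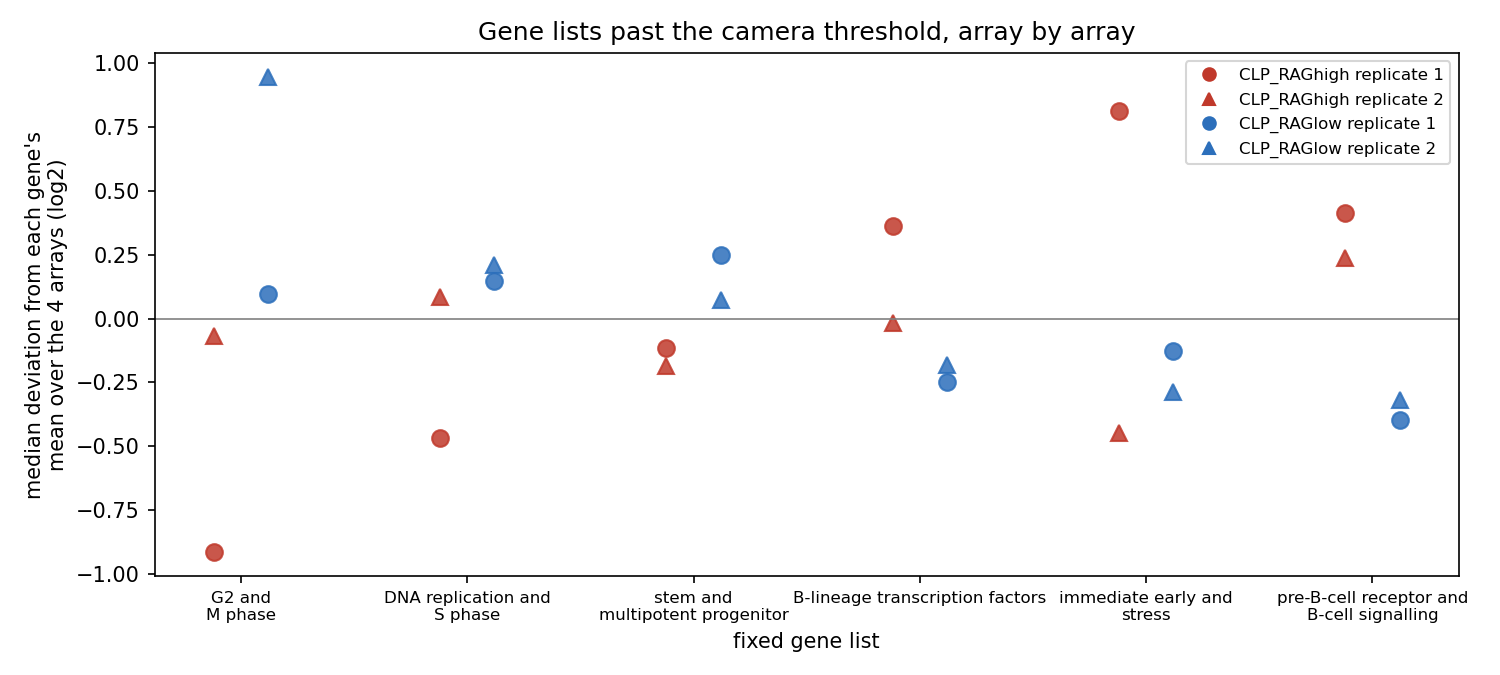
Median log2 deviation of the genes of each list from their own mean over the 4 arrays (vertical axis), for the 6 lists past the camera threshold, with symbols and colours for the arrays. For pre-B-cell receptor and B-cell signalling the CLP_RAGhigh arrays sit at 0.41 and 0.24 and the CLP_RAGlow arrays at -0.40 and -0.32, while for immediate early and stress genes CLP_RAGhigh replicate 1 alone is high, at 0.81.

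The remaining 12 lists did not pass with camera. V(D)J recombination and end joining genes had a median difference of 0.06 over 11 genes (adjusted p = 0.101, and a median from 0.023 to 0.36 when 1 array was left out), with 1 gene, Rag1, passing over the list alone. Xrcc6 differed by 0.57 ± 0.21 and Prkdc by -1.02 ± 0.55. Of the 11 genes, 6 had a higher and 5 a lower mean in CLP_RAGhigh. Rag1 and Rag2, after which the groups are named, are among them, so an upward result may in part follow from the sort. This list passed upward without CLP_RAGhigh replicate 2 (adjusted p = 0.0336) and without CLP_RAGlow replicate 1 (adjusted p = 0.0450). Lymphoid-primed progenitor genes had a median of 0.14 over 15 genes (adjusted p = 0.122), which was 0.039 without CLP_RAGhigh replicate 1 and 0.068 with probe sets averaged, with Il7r, the interleukin-7 receptor chain, at means of 11.23 and 10.42, Ikzf1 at 10.96 and 10.54, and Ets1 and Cd53 at differences of 0.63 and 0.28. The Ets1 and Cd53 differences turn to -0.13 and -0.68 when all probe sets of a gene are averaged.

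Lists of other lineages did not pass as groups, and with limma 0 T-lineage, dendritic cell or natural killer genes passed over their list alone. T-lineage genes had a median of 0.12 over 19 genes (adjusted p = 0.483), with values in both directions. Cd247 and Hes1, a target of Notch signalling, had values of 1.31 ± 0.35 (0.42 with probe sets averaged, 1 of the 4 at -0.098) and 1.79 ± 0.52, and Cd28 and Cd6 of -2.89 ± 0.86 (-1.26 with the offset of 32) and -1.01 ± 0.34. Dendritic cell genes had a median of -0.28 over 17 genes (adjusted p = 0.218), with Irf8 at -0.65 ± 0.26, Cox6a2 at -1.06 ± 0.43, Bst2 at -0.90 ± 0.39 and Ccr9 at -0.76 ± 0.49 (-0.35 with probe sets averaged). This list passed downward when genes below the median brightness were left out (adjusted p = 0.0439), and its median was -0.066 without CLP_RAGhigh replicate 1. Natural killer and innate lymphoid genes had a median of 0.08 and a mean of -0.03 over 20 genes (adjusted p = 0.921, test direction downward), with Id2, an inhibitor of E proteins, at -0.88 ± 0.39 (-0.26 with probe sets averaged, 1 of the 3 at 0.28), Nfil3 at -0.89 ± 0.36, Klrd1 at 0.73 ± 0.42 and Prf1 at 0.59 ± 0.39 (0.21 with the offset and 0.24 with probe sets averaged).

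Granulocyte and monocyte genes had a median of 0.03 and a mean of 0.18 over 24 genes (adjusted p = 0.921, test direction downward). Csf1r, the receptor of macrophage colony-stimulating factor, had means of 7.52 and 9.42, a difference of -1.90 ± 0.52, Csf3r differed by -0.83 ± 0.36, Lyz1 by -0.74 ± 0.33 (-0.040 without cross-hybridising probe sets) and Fcgr3 by 0.40 ± 0.21 (0.09 with the offset of 32). With the preset correlation the list passed upward without CLP_RAGlow replicate 1, with a median of 0.15. The same list passed downward without CLP_RAGlow replicate 2, with a median of -0.39. The call and its direction therefore depended on which CLP_RAGlow array was kept. Its median deviation from each gene's mean was 0.37 and -0.14 on CLP_RAGhigh replicates 1 and 2. On CLP_RAGlow replicates 1 and 2 it was 0.29 and -0.15, so the list as a whole divided by replicate number. S100a8, a neutrophil gene picked after its values were seen, had log2 intensities of 9.63, 9.60 and 10.15 on the other 3 arrays and 3.81 on CLP_RAGlow replicate 2. Erythroid and megakaryocyte genes had a median of 0.04 over 18 genes (adjusted p = 0.796). Adjusted over the list alone 1 of them passed, Gfi1b, a transcriptional repressor expressed in these lineages and in stem cells, which fell by 1.94 ± 0.37 in CLP_RAGhigh, while Klf1, Pf4 and Aqp1 differed by 2.02, 0.48 and 0.45, of which Pf4 and Aqp1 are dim (0.13 and 0.15 with the offset).

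Interferon-stimulated genes had a median of -0.23 over 14 genes (adjusted p = 0.732), with Rsad2, an antiviral enzyme, at means of 7.14 and 8.69 (a difference of -1.55, and -0.58 with probe sets averaged, 1 of the 3 at 0.29), Usp18 at 0.91 ± 0.39, Mx1 at 0.62 ± 0.41 and Stat2 at -0.46 ± 0.25 (-0.16 with the offset and -0.17 with probe sets averaged). The BCL2 family had a median of 0.10 over 14 genes (adjusted p = 0.921), in which the survival factor Bcl2 had means of 8.58 and 9.38 and Mcl1, Bmf and Bbc3 were at 0.24, 0.57 (0.27 with probe sets averaged) and 0.41. MYC and ribosome biogenesis genes had a median of -0.06 and a mean of 0.00414 over 20 genes (adjusted p = 0.921, test direction downward), with Myc at 0.60 ± 0.31, Odc1 at -0.43 ± 0.21, Fbl at -0.34 ± 0.17 and Ncl at 0.23 ± 0.14 (0.0092 with probe sets averaged). Mature B and plasma cell markers had a median of 0.01 over 13 genes (adjusted p = 0.921), with Sdc1 and Cd37 at 0.64 and 0.87, Tnfrsf13b at -0.98 and Jchain at 0.58 (0.12 with the offset of 32). For Sdc1 the difference was 0.42 with probe sets averaged and 0.24 without cross-hybridising ones. Stromal and endothelial markers had a median of 0.02 and a mean of -0.03 over 14 genes (adjusted p = 0.921, test direction downward), with Pdgfrb at -0.28 and Col1a2, Col3a1 and Cdh5 at -0.58, 0.15 and -0.13. These last 3 were dim in at least 1 group, and with the offset their differences were -0.21, 0.02 and -0.02.

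Among the sex-linked genes, Xist differed most between arrays of a group. Xist, the noncoding RNA of the inactive X chromosome, had log2 intensities of 6.28 on CLP_RAGhigh replicate 1, 9.82 on CLP_RAGhigh replicate 2, and 10.39 and 10.05 on the CLP_RAGlow arrays. The Y-linked genes Eif2s3y and Kdm5d were between 6.93 and 9.23 on the 4 arrays. Xist and these 2 genes thus lay above 3.90, the limit for dim genes, on all 4 arrays. By these genes no array had the signal of 1 sex alone, although Uty was at 1.96 and 3.68 on the CLP_RAGlow arrays. The labels do not say whether male and female animals were pooled. Uty, also Y-linked, differed by 2.47 ± 0.65 (0.85 with the offset of 32, and 0.68 with its 4 probe sets averaged, of which 1 was at -0.12), with a limma adjusted p of 0.745. The array low in Xist, CLP_RAGhigh replicate 1, is one without which the immediate early, S phase and B-lineage transcription factor calls were lost. The immediate early call was also lost without CLP_RAGlow replicate 2 (adjusted p = 0.190).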

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

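The setting that joins an offset of 32 with the estimated correlation, and the one that takes the stress genes out of the background, were chosen after the data were seen. With limma the count of genes higher in CLP_RAGhigh was 0 in 12 of 17 alternatives and that of genes lower was 0 in 13 of 17. It became 2 higher when the probe sets of a gene were averaged, 5 higher and 1 lower when genes below the median brightness were left out, 2 higher and 1 lower after a second quantile normalization, and 6 higher and 2 lower at an adjusted p under 0.1. With the replicate block, 5 genes were higher and 2 lower, and 6 lists passed. The deviations of same-numbered arrays from their group means had a correlation of -0.0248 across genes. With 2 arrays per group both pairs give this same value, so they are not independent. The labels do not say that a number is shared. The genes past 0.05 in at least 1 alternative included 7 named ones, among them Pou2af1, Gpat3 and Vpreb1. The 6 lists became 0 with the estimated correlation, with fry's directional test and with the offset of 32 and the estimated correlation together, and ranged from 3 to 8 when 1 array was left out. For G2 and M phase genes and pre-B-cell receptor and B-cell signalling, 16 of 19 alternatives kept the call, the exceptions being these 3. Stem genes, S phase genes and B-lineage transcription factors kept it in 15 of 19, each also losing it without 1 array, and the stress genes in 8 of 18. Camera has no robust variance model, so that alternative gave no list result. With all probe sets averaged, Ets1 turned to -0.13, Cd53 to -0.68 and the MYC list to a median of 0.077. With each probe set on its own the MYC list was at 0.065 and the granulocyte list at -0.0077. Without cross-hybridising probe sets, Rrm2 was at 0.054, Bmf at -0.076 and the MYC list at 0.15. Without genes below the median brightness, the natural killer list was at -0.035, the erythroid list at -0.29, the BCL2 family at -0.033 and the stromal list at -0.15. Leaving out 1 array at a time turned the sign of lists not called in the main test. Medians ran from -0.12 to 0.21 for T-lineage, -0.15 to 0.075 for natural killer and -0.39 to 0.33 for granulocyte genes. The granulocyte list passed upward without CLP_RAGlow replicate 1 and downward without CLP_RAGlow replicate 2. Ranges were -0.062 to 0.088 for erythroid, -0.27 to 0.11 for interferon and -0.15 to 0.29 for BCL2 genes. They were -0.078 to 0.20 for MYC, -0.076 to 0.091 for mature B and -0.19 to 0.12 for stromal genes. The sign also turned for Col1a2 (-1.19 to 0.024), Col3a1 (-0.028 to 0.33) and Eif2s3y (-0.10 to 0.84). The cause of these changes was not tested. The remaining named genes, 84 of 91, kept their direction in every alternative, but for many alternatives this was fixed in advance. The variance models, the filters on dim genes, the replicate block and each probe set on its own reuse the same difference. For genes whose groups do not overlap, the offset or leaving out 1 array cannot turn the sign. Of the 53 named genes with several probe sets, 23 had at least 1 in the other direction. Signal over background limits dim genes, whose log2 differences shrink with the offset.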

Other observations

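The tests of brightness, of RNA quality, of the G2 and M phase genes and of the GIMAP family were chosen after the results were seen, and the genes of the next paragraph were chosen after their values were seen. The brightness test and both G2 and M phase tests replaced first forms that had counted against all 3 explanations, and their limits were written with those results known. For the G2 and M phase tests a limit out of reach with 2 arrays per group was also tried and dropped, and while it stood both explanations were left open.

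Several bright genes outside the fixed lists separated the groups, none past the limma threshold over all genes. Toward CLP_RAGhigh, Pde2a, a phosphodiesterase, had mean log2 intensities of 11.92 and 9.54, a difference of 2.38 ± 0.30 (SE, n = 2 per group), and Pik3r6, a regulatory subunit of phosphoinositide 3-kinase gamma, differed by 2.35 ± 0.28. Mzb1, a chaperone of antibody-secreting B cells, differed by 2.24 ± 0.33, Chchd10, a mitochondrial protein, by 2.05 ± 0.26, and Trem1 by 2.91 ± 0.44. Parp1, a DNA repair enzyme, was at 0.93 ± 0.13, Pnp at 0.87 ± 0.13 and Dck at 0.83 ± 0.18. Toward CLP_RAGlow, Kif22, a mitotic kinesin, differed by -1.43 ± 0.23, Ndrg1 by -1.91 ± 0.34, Marveld1 by -1.97 ± 0.30, Gsn, which encodes the actin-severing protein gelsolin, by -2.46 ± 0.49 and Wfdc17 by -2.54 ± 0.47. The interleukin receptor genes Il1r1 and Il17re differed by -1.25 ± 0.39 and -1.14 ± 0.44.

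GIMAP genes, GTPases expressed in lymphocytes, had higher means in CLP_RAGhigh. Without Gimap4, which drew attention to them, 7 of 7 other members had a higher mean, with differences from 0.26 to 1.68 and a median of 0.85. Limma's camera over these 7 genes gave p = 1.5e-05 with the preset correlation, and p = 0.118 with an estimated correlation. Gimap8 had means of 10.99 and 9.31 and Gimap7 of 9.22 and 8.37. Since this test was thought of after the values were seen, and its p with an estimated correlation is above 0.05, a shift of the family stays open. For the PYHIN genes, a family of cytosolic DNA sensors, Ifi213 and Ifi209 differed by 3.36 and 1.88, but the 6 other members had a median of 0.08. Limma's camera gave p = 0.0555 for these others with the preset correlation and p = 0.189 with an estimated correlation. Before the values were seen, a p of 0.05 or more had been set to count against a shift of the family, which this p meets. That limit was set aside after the result was seen, because a p that misses a threshold does not show that the genes did not differ, so the question stays open.

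The 7 neutrophil genes S100a8, S100a9, Ngp, Camp, Ltf, Lcn2 and Chil3, picked for this pattern, were low on CLP_RAGlow replicate 2, as Ngp shows with 9.01, 9.72 and 10.38 on the other 3 arrays and 3.80 there, whereas Elane was 4.01 there and 3.91 on CLP_RAGlow replicate 1, and Prtn3 and Ctsg were 6.70 and 6.45 there and 4.69 and 6.41 on CLP_RAGhigh replicate 2. A weaker signal of all genes of that brightness is argued against, since 2157 other genes of similar brightness had a median gap of 0.014 (quartiles -0.36 and 0.31), where the 7 genes had 4.28. RNA from neutrophils or their precursors in the other 3 samples may be a source. In a test set before the values were seen, 10 of 18 other measured neutrophil genes were lowest on CLP_RAGlow replicate 2. The exact binomial p was 0.00542 (one-sided), but it takes the genes as independent, and genes that vary together may make it too small. The median gap was 0.25, below what was set for that explanation, and several of these genes were near the floor. That explanation stays open, since the test met its limit for the count of genes but not for the gap. Mpo, of the granulocyte list, was at 10.91, 10.88, 10.70 and 11.03 on the 4 arrays, and the sort for CLP is meant to exclude mature neutrophils.

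Some immediate early and heat shock genes, picked for this, were high on CLP_RAGhigh replicate 1, with Hspa1b at 10.70 there against 1.99, 2.44 and 4.17, and Jun at 9.08 against 5.61, 5.79 and 5.20, but on that array and CLP_RAGlow replicate 1 Egr1 was 6.48 and 6.28, Rhob 8.46 and 8.24, and Socs3 6.29 and 6.93. The 3' to 5' ratio of Actb on that array, 16.2, lay within the range of the other 3 (9.62 to 24.5). That of Gapdh, 15.7, did too. CLP_RAGlow replicate 2, with the highest ratios, had Hspa1b at 4.17 and Jun at 5.20. With 4 arrays, an array often lies within such a range, so this test cannot exclude poorer RNA or amplification. A stress response of the cells, for example during sorting, may be a source. In a test set before the values were seen, 10 of 19 other stress-induced genes were highest on that array. The exact binomial p was 0.0089 (one-sided), but it too takes as independent genes that may vary together. The median gap was 0.23, below the 0.5 set for a stress response. That leaves it open.

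Whether CLP_RAGhigh replicate 1 alone makes the lower level of G2 and M phase genes in CLP_RAGhigh cannot be told, since the list's median in CLP_RAGhigh replicate 2 was -0.12 against CLP_RAGlow replicate 1 and -0.94 against CLP_RAGlow replicate 2. Less labelled RNA on CLP_RAGhigh replicate 2, whose hybridisation controls were bright, is argued against as the whole cause, since the list's median in CLP_RAGhigh replicate 1, without that sign, was -1.33 and -2.17 against the same arrays, although this rests on 1 array. The poly-A controls were brighter on both CLP_RAGhigh arrays (1392 and 1572) than on the CLP_RAGlow arrays (1129 and 1023). Less sample RNA on both CLP_RAGhigh arrays was not tested. The first forms used the median against the CLP_RAGlow mean, -0.52 and -1.61 (adjusted p = 0.00171 and 2.4e-10 by limma's camera with the preset correlation), with a binomial test over genes that vary together, and were replaced for that reason. A slower cycle of CLP_RAGhigh cells is a hypothesis that these values may fit, but the arrays of each group differ by nearly as much as the groups. Among the 3 ways to split the 4 arrays into 2 and 2, 1 split, the real one, gave 6 lists, and the split by replicate number gave 4, the S phase, granulocyte, stress and G2 and M phase lists (adjusted p = 1.0e-06 for the last), and the other split gave 0, while with 3 splits no share under 0.05 can be had.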
